A study of Mus musculus with 6 samples.

How the data were processed

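RNA-seq libraries were made from liver lymphocytes of mice, 3 from animals given oil and 3 from animals given tamoxifen. Per the labels' protocols, the cells were lysed, RNA was reverse transcribed with a SMARTer Ultra Low RNA kit and the cDNA was amplified by PCR with an Advantage 2 kit. The protocol text speaks of single cells, and the number of cells per library, the number of animals behind each library, the genotype and the doses are not given in the sources used here. Where nothing says that libraries came from separate animals, p-values measure only the spread between these libraries, which may be technical. The kit adds no molecular identifiers, so counts after PCR are not counts of independent molecules.

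One table of the whole series was used. It holds, per the file headers, a count and an FPKM value per gene and library, and the authors' mean FPKM per group with a p-value and a q-value for tamoxifen against oil. The counts are whole numbers as deposited, with no normalization. The FPKM values were made by the authors from those counts: for 7282 genes with 50 or more counts in every library, the ratio of count to FPKM followed the library totals within 0.0001. The authors' p-values and q-values come from a comparison that the table's name attributes to edgeR; the kind of test is not given in the sources used here. The submitters' processing notes list HISAT2, StringTie and the build mm10, with no roles, versions or annotation. The strand setting, the counter and the treatment of reads that match more than 1 gene are not given in the sources used here; Gapdh, which has many processed pseudogenes, stood at 8.52 ± 0.489 CPM in the oil libraries. Families with near-identical copies, such as Hspa1a and Hspa1b, the Klra genes and Ly6c2, are uncertain for this reason. The table's own log2 column held text in place of some values and was not used here.

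The table lists 15601 genes with Ensembl identifiers, each with at least 2 counts over the 6 libraries. Of these, 15528 were found in GENCODE release M21 on the same chromosome, 12155 with identical coordinates. Gene symbols and coordinates are those of the table, except for 20 symbols that had been turned into dates and were replaced through their identifiers. Library totals were 5289803 to 6325899 counts. A gene at 0 in a library could still be present at up to 0.474 to 0.567 CPM (3 counts), from counting error alone.

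The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM normalization, the default expression filter by group and group as the only term, in all 6 libraries; a gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled with the TMM factors, and standard errors were taken from the quasi-likelihood F statistic. Gene lists were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 3 tested genes, and beside it with camera at an estimated correlation and with fry. Single values of 3 against 3 libraries were compared by exact permutation tests, two-sided, for which the smallest p is 0.1. The tests, the 32 lists, the rule for named genes and 18 of the 19 alternative fits for genes were set before the data were examined. The named genes were Rora; the genes past the threshold with a 2-fold change, a symbol that is not a predicted model or pseudogene and groups that did not overlap, up to 12 per direction; where fewer than 5 passed in a direction, the 10 with the smallest p under the same other conditions, given as not passing; and from each list the passing members, up to 4, or else the 2 with the smallest p. Other genes were named after their values were seen. Some genes that the rule or a list would name are not reported here.

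The lists covered ILC1 identity, conventional NK cell markers, cytotoxicity, effector cytokines and chemokines, cytokine receptors and JAK-STAT, homing and tissue retention, memory and stemness, lymphoid transcription factors, activating and inhibitory receptors, cell cycle, apoptosis and survival, circadian clock and ROR-responsive genes, cholesterol synthesis and uptake, fatty acid metabolism, glycolysis, oxidative phosphorylation, interferon response, immediate early and dissociation stress genes, the NF-kB and TGF-beta pathways, oestrogen receptor targets and mitochondrially encoded genes. Markers of T cells, B cells, macrophages and Kupffer cells, neutrophils, dendritic cells, hepatocytes, liver endothelium, erythroid cells and platelets, ILC2s and ILC3s formed 10 further lists. Some marker genes are also expressed by ILC1s or NK cells, among them Ccr2, Itgax and the Cd3 genes.

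Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 counts in every library of a group, a 2-fold threshold, the replicate number as a block, limma on log2 FPKM with pseudocounts of 1 and 0.1 and without a filter, protein-coding genes only, leaving out each library in turn, and, chosen after seeing the data, the length trend of each library as a covariate. This trend is the slope of a library's log2 CPM, relative to the mean of all libraries, on log2 gene model length. Overlapping exons were looked up in GENCODE M21 for 94 genes, and 29 shared exon bases with another gene. The tests were tried on simulated counts with the means, library sizes and dispersions of these libraries (10811 genes, 5 draws with 200 changed genes each): 27.3% of genes changed 2-fold and 77.5% of genes changed 4-fold were called, and 6.48% of calls were false. With the cholesterol list lowered 1.5-fold in 20 draws, camera called it in 20, and 2 of 600 tests of unchanged lists were called. The simulated genes varied independently of each other, a setting that favours camera's preset correlation. Exact tests of library totals used scipy 1.17.1 in Python 3.11.15.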

Results

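Gene expression was measured in liver lymphocytes of mice given oil, the vehicle, or tamoxifen, a ligand of oestrogen receptors that is also widely used to switch on inducible Cre recombinases. The study's title names type 1 innate lymphoid cells (ILC1s), which in liver are largely tissue-resident and form group 1 innate lymphoid cells together with natural killer (NK) cells, whereas the labels call the cells lymphocytes. The series concerns RORα, the nuclear receptor encoded by Rora, and its only contrast was tamoxifen against oil. There were 3 libraries per group. The oil libraries held 6325899, 5289803 and 5675362 counts and the tamoxifen libraries 5535609, 5849947 and 5358622, with 13060 to 13414 genes counted at least once in each. Total counts did not separate the groups (exact permutation test, two-sided, p = 0.7, where 0.1 is the smallest value that 3 against 3 allows).

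The cells of all 6 libraries carried transcripts of the ILC1 and NK lineage at high levels. Ncr1, which encodes the activating receptor NKp46, stood at 1227 ± 127 CPM (counts scaled to library size; SD, n = 3) in oil and 1241 ± 91.1 in tamoxifen, and Klrb1c, which encodes NK1.1, at 787 ± 67.1 and 944 ± 70.7. Tbx21, the gene of the transcription factor T-bet, stood at 262 ± 146 and 184 ± 76.6 CPM. Eomes, a transcription factor of conventional NK cells, was present in both groups at 121 ± 35.4 and 115 ± 28.1 CPM.

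Rora itself was the first gene of interest, because the study's title names its product. Rora (ENSMUSG00000032238; mm10 chromosome 9, 68653786 to 69388246, plus strand) stood at 27.7, 24.9 and 19.9 CPM in the oil libraries and at 18.3, 13.4 and 20.4 CPM in the tamoxifen libraries, from 422 and 287 counts in all. The group means were 24.2 ± 3.92 and 17.4 ± 3.60 CPM (SD, n = 3), a log2 fold change of -0.48 (SE 0.28). The groups overlapped, and the difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.999; exact permutation test, two-sided, p = 0.2). The counts cover the whole gene and so do not show whether single exons were lost, and the labels used here give no genotype.

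The comparison of tamoxifen with oil showed 1 gene past the threshold, Serpine2, which encodes protease nexin-1, a secreted inhibitor of serine proteases. Serpine2 (chromosome 1, 79794197 to 79861180, minus strand) rose from 27.7 ± 13.0 CPM in oil to 177 ± 24.2 CPM in tamoxifen, a 6.35-fold difference with every tamoxifen library above every oil library. Phlda3, a p53-induced repressor of AKT signalling, stood at 1.29 to 6.04 CPM in oil and at a mean of 30.3 ± 6.95 CPM in tamoxifen without passing. Asb2, a substrate receptor of a ubiquitin ligase, stood at 222 ± 80.9 CPM in oil and 46.9 ± 12.1 in tamoxifen, again without passing. Of 10811 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1 higher (Serpine2, log2 fold change 2.67, SE 0.30, adjusted p = 0.0313) and 0 lower. At an unadjusted p under 0.05 there were 381 genes, 184 higher and 197 lower, where chance alone gives 541. The count depended on the fit. With 1 library left out it was 282 (without tamoxifen replicate 3) to 888 (without oil replicate 3). With the length trend of each library as a covariate it was 756. In the main fit, 8.87% of genes had groups that did not overlap, against 10% by chance. DESeq2 called 18 genes on the same counts, 6 higher and 12 lower. The call of Serpine2 ended without tamoxifen replicate 2 (adjusted p = 0.0763 by the same edgeR test) and without tamoxifen replicate 3 (adjusted p = 0.173), with the replicate number as a block (adjusted p = 0.0677), and with limma on log2(FPKM + 1), on log2(FPKM + 0.1) and on log2(FPKM + 1) with no filter (adjusted p = 0.0571, 0.109 and 0.193). Its log2 fold change was 2.44 to 3.12 over the 6 fits that each left out 1 library. Those fits called 2, 3 and 4 genes without oil replicates 1, 2 and 3, and 6, 1 (Gemin4) and 0 without tamoxifen replicates 1, 2 and 3.

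**Figure D1:**
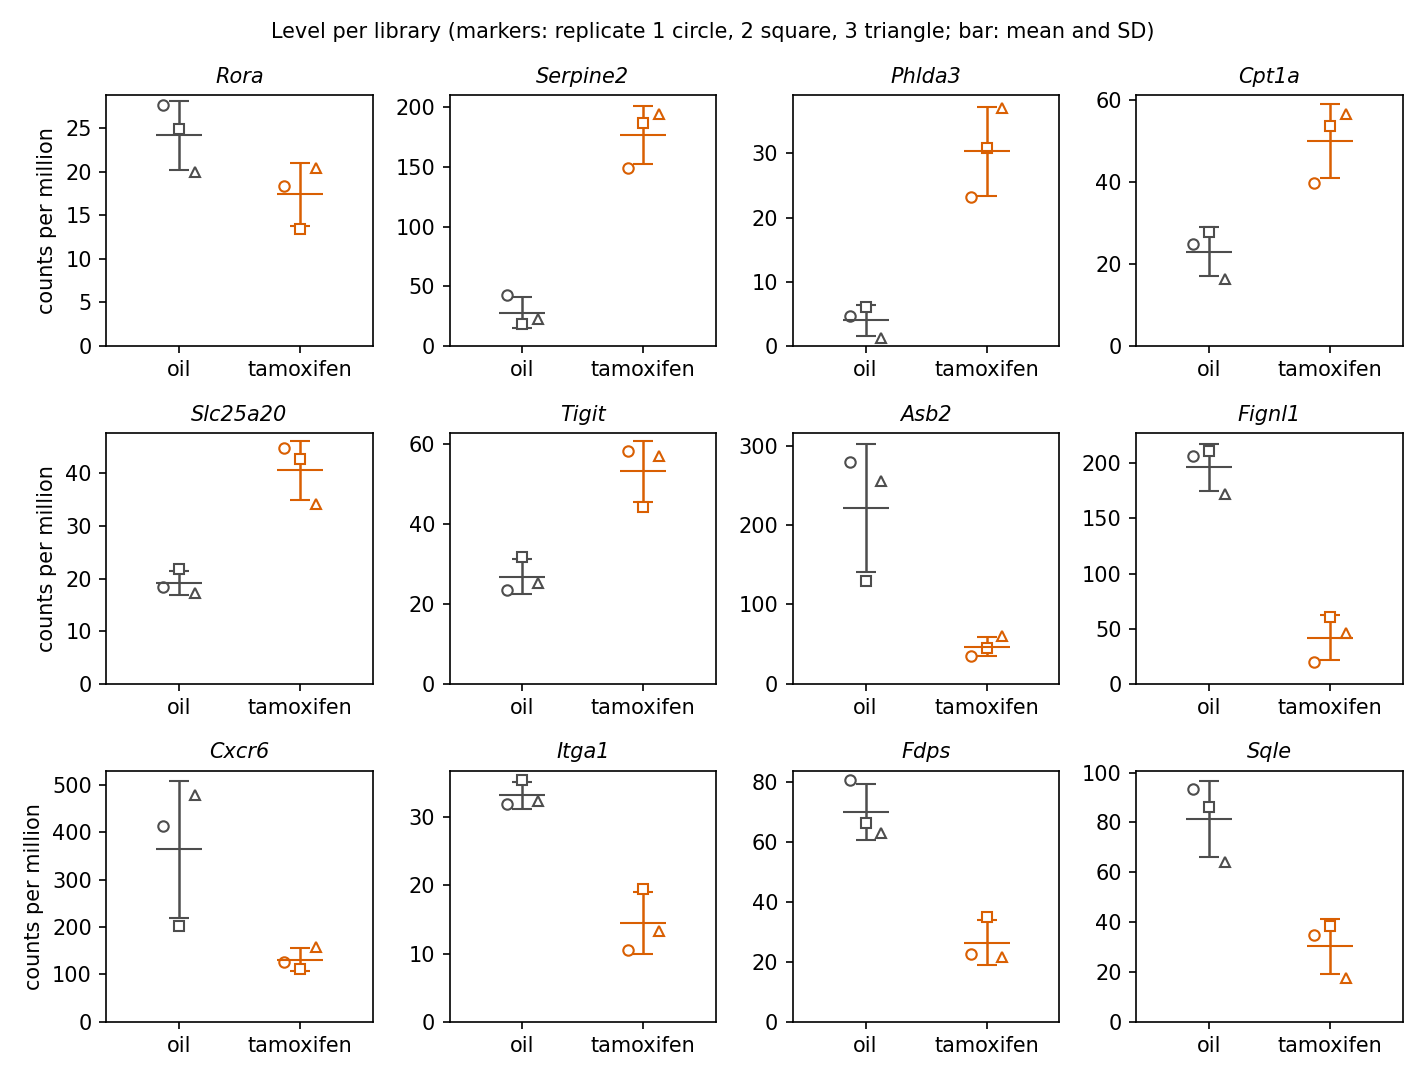
Level of 12 genes in each library in CPM (vertical axes from 0), with oil libraries in grey and tamoxifen libraries in orange; each point is a library, and the bars give the mean and SD of 3. Serpine2 stood at 18.1 to 42.4 CPM in oil and at 149 to 194 CPM in tamoxifen, whereas the groups overlapped for Rora.

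The other genes that separated the groups by at least 2-fold did not pass the test and are given as values. Besides Serpine2 and Phlda3, the smallest p-values among higher genes belonged to Phactr3 (log2 fold change 1.69, SE 0.32), Sele (2.53, SE 0.56), which encodes E-selectin, Lif, Slc25a20 (1.08, SE 0.25), AA467197 (1.42, SE 0.33), Tnfsf4 (1.70, SE 0.40), which encodes OX40 ligand, Cpt1a (1.12, SE 0.28) and Tmsb10 (1.04, SE 0.26), an actin-binding thymosin. Slc25a20 and Cpt1a encode the mitochondrial carnitine carrier and the acyltransferase that together bring long-chain fatty acids into mitochondria; Slc25a20 stood at 19.2 ± 2.32 and 40.6 ± 5.65 CPM and Cpt1a at 22.9 ± 5.98 and 49.9 ± 9.04 CPM. Lif, a cytokine of the interleukin-6 family, had 2 counts over the oil libraries and 55 over the tamoxifen libraries, a ratio of 28.6 after scaling to library size (95% exact binomial interval 7.54 to 242). Among lower genes they included Asb2 (log2 fold change -2.24, SE 0.30), Fignl1 (-2.22, SE 0.34), an ATPase of homologous recombination, Jmjd8 (3.99-fold lower, SE of log2 fold change 0.32), Fdps (-1.40, SE 0.26), Cxcr6 (-1.47, SE 0.29), Carm1 (-1.77, SE 0.35), an arginine methyltransferase, Hspa1b, Sqle (-1.42, SE 0.30) and Zfp422 (-3.15, SE 0.67). Asb2 had an adjusted p of 0.0684 and Fignl1 of 0.110 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hspa1b, an inducible heat shock gene with a near-identical neighbour, Hspa1a, had 116 counts over the oil libraries and 2 over the tamoxifen libraries, a ratio of 55.9 (95% exact binomial interval 15.1 to 467). These intervals cover counting error only; of the 116 counts 79 came from oil replicate 2, and over the fits that left out 1 library the log2 fold change was -8.26 (without tamoxifen replicate 2) to -4.46 (without oil replicate 2) for Hspa1b and 4.02 (without oil replicate 1) to 7.25 (without oil replicate 3) for Lif. Exons of Jmjd8 and of Stub1 on the opposite strand share 39.3% of the exon bases of Jmjd8. Those of Carm1 and of Yipf2, also on the opposite strand, share 21.1% of Carm1. The strand setting of the counting is not given in the sources used here. Exons of Fdps and of a readthrough model on the same strand, Gm43738, share 26.7% of Fdps.

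Cholesterol genes were lower after tamoxifen as a group. Of 24 genes of cholesterol synthesis and uptake, 23 had a lower estimate in tamoxifen, with a median log2 fold change of -0.63 and a mean of -0.67. Relative to oil, the mean level of the list was -0.51, -0.66 and -0.94 (log2) in tamoxifen replicates 1, 2 and 3, while the oil libraries lay between -0.04 and 0.07. None of the 24 passed over all genes, and 8 passed when adjusted over the list alone, all lower, among them Fdps, Sqle, Hmgcs1, Cyp51, Insig1, Msmo1 and Fdft1. They span the pathway, from Hmgcs1 at the entry to the mevalonate pathway, through Fdps and Fdft1 at the branch to squalene, to Sqle, Cyp51 and Msmo1, which turn squalene into sterols. Fdps stood at 69.9 ± 9.35 CPM in oil and 26.4 ± 7.39 in tamoxifen, and Sqle at means of 81.4 and 30.3 CPM. In 11 of the 24 genes every tamoxifen library lay below every oil library. Exons of Fdft1 and of Ctsb on the opposite strand share 18.3% of the exon bases of Fdft1, and the strand setting is not given. Srebf2, the gene of the transcription factor that drives the pathway, had a log2 fold change of -0.64 (SE 0.27). The list was called by camera with its preset correlation (adjusted p = 2.11e-14 over 31 lists) and by fry (adjusted p = 0.0256), but not by camera with an estimated correlation (adjusted p = 0.0518). The list was called in all 6 fits that left out 1 library (camera with the preset correlation, adjusted p = 2.29e-14 to 2.40e-08).

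**Figure D2:**
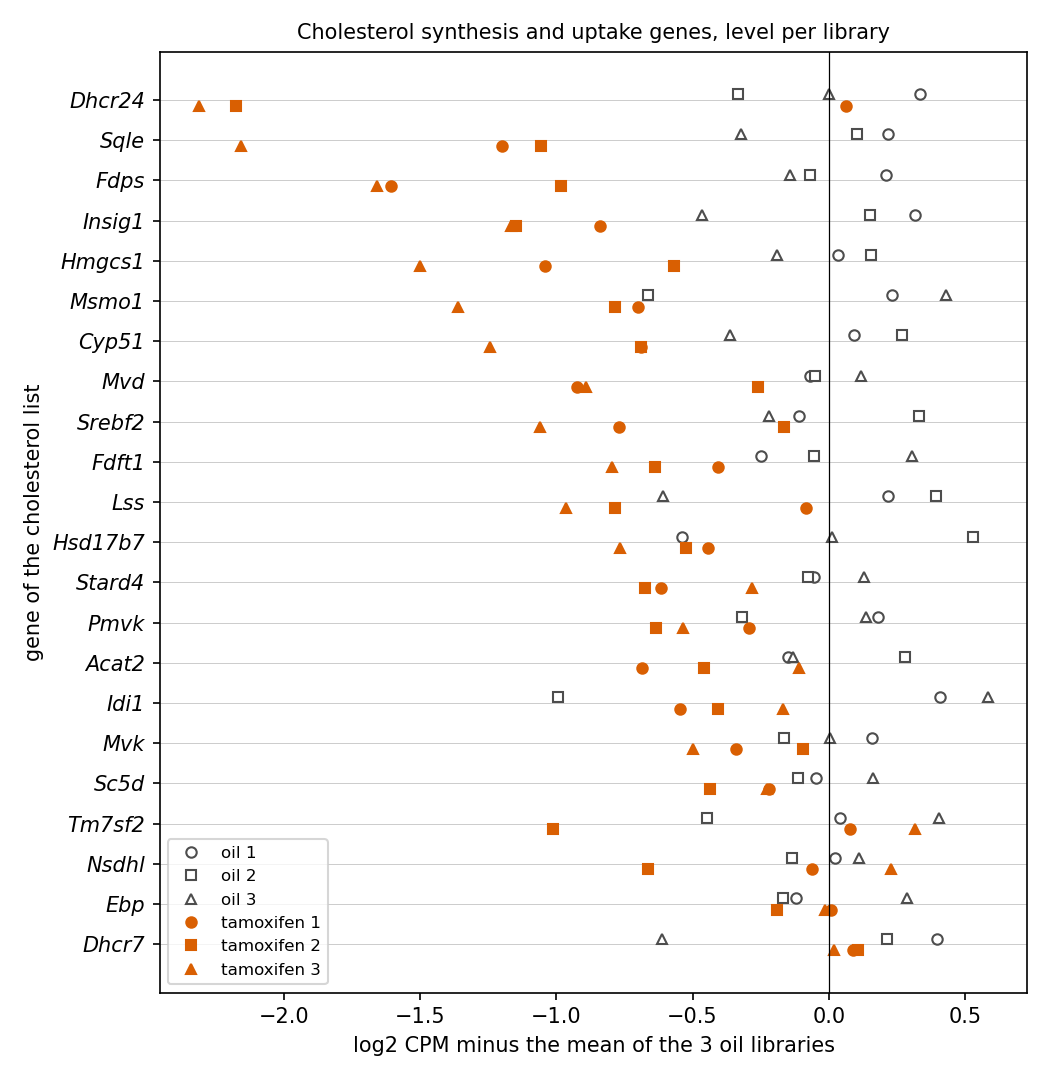
Level of genes of the cholesterol list in each library, as log2 CPM minus the mean of the 3 oil libraries (horizontal axis), 1 gene per line. Open grey symbols are oil libraries and filled orange symbols tamoxifen libraries; Fdps and Sqle were among the genes with every tamoxifen library left of every oil library, and Dhcr7 was the gene with a higher estimate in tamoxifen (log2 fold change 0.01).

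Genes of the NF-kB pathway were lower in tamoxifen in 17 of 22 cases, with a median log2 fold change of -0.20. None passed over all genes and 3 passed when adjusted over the list alone, all lower: Relb (67.7 ± 3.06 against 38.6 ± 6.56 CPM; log2 fold change -0.81, SE 0.22), Nfkb2 (97.7 ± 24.6 against 50.0 ± 13.7 CPM; -0.96, SE 0.26) and Bcl3 (116 ± 11.1 against 69.7 ± 15.9 CPM; -0.73, SE 0.21). Relb and Nfkb2 encode the subunits of the non-canonical pathway, whereas Rela and Nfkb1, of the canonical pathway, had log2 fold changes of 0.12 (SE 0.17) and 0.53 (SE 0.28). Camera called the list with its preset correlation (adjusted p = 0.0031), but not with an estimated correlation (adjusted p = 0.686), and fry did not call it (adjusted p = 0.629). The preset call also ended without oil replicate 2 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0532) and without tamoxifen replicate 1 (adjusted p = 0.062).

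All 13 mitochondrially encoded genes had higher estimates in tamoxifen, with a median log2 fold change of 0.23, and none passed on its own, whether over all genes or over the list alone. The smallest p-values belonged to mt-Nd6 (log2 fold change 0.40, SE 0.24) and mt-Co1 (0.26, SE 0.20). The share of counts from these genes was 0.689%, 0.779% and 1.25% in the oil libraries and 1.11%, 0.987% and 1.17% in the tamoxifen libraries, so oil replicate 3 lay above every tamoxifen library. Camera called the list with its preset correlation (adjusted p = 0.00608), but not with an estimated correlation (adjusted p = 0.826), and fry did not (adjusted p = 0.827). Without oil replicate 1, oil replicate 2, tamoxifen replicate 1 or tamoxifen replicate 3 the adjusted camera p was 0.323, 0.403, 0.0664 and 0.168, and with the length trend of each library as a covariate it was 0.0884.

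The other 28 lists tested passed neither with a preset nor with an estimated correlation (adjusted camera p = 0.355 to 0.989 with the preset value). The ILC1 identity list was mixed, with 8 genes higher and 9 lower (median log2 fold change -0.06). Its members Cxcr6, the chemokine receptor that holds lymphocytes in liver sinusoids, and Itga1, which encodes CD49a, the integrin that marks liver ILC1s, passed when adjusted over the list alone. Cxcr6 stood at 364 ± 145 CPM in oil and 131 ± 23.3 in tamoxifen, and Itga1 at 33.2 ± 1.97 and 14.5 ± 4.60 (log2 fold change -1.19, SE 0.29). The conventional NK cell list had 9 gene models higher and 12 lower (median -0.07), Itgam being counted under 2 overlapping models, and Ly6c2 (-0.58, SE 0.21) and Itga2 (-0.90, SE 0.38), which encodes CD49b, had its smallest p-values. The cytotoxicity list had 13 genes higher and 7 lower (median 0.11), with Serpinb6b at 0.34 (SE 0.17) and Gzmc at -1.03 (SE 0.59). Of effector cytokines and chemokines, 3 were higher and 10 lower (median -0.14), with Osm at 0.52 (SE 0.19) and Xcl1 at -0.70 (SE 0.30). Cytokine receptors and JAK-STAT genes were 13 higher and 16 lower (median -0.08), with Il7r, the interleukin-7 receptor, at 1.01 (SE 0.33) and Socs2 at 0.59 (SE 0.20).

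Homing and tissue retention genes were 10 higher and 15 lower (median log2 fold change -0.09), and Cxcr6 and Itga1 were the 2 that passed over that list alone. Memory and stemness genes were 8 higher and 7 lower (median 0.05), with Il7r and the transcription factor gene Lef1 (0.58, SE 0.19) first. Lymphoid transcription factors were 11 higher and 22 lower (median -0.16), with Tox at -0.73 (SE 0.21). Among activating and inhibitory receptors, 14 were higher and 10 lower (median 0.03); Tigit, an inhibitory receptor of NK and T cells, passed over the list alone, at 26.8 ± 4.43 and 53.1 ± 7.70 CPM (log2 fold change 0.99, SE 0.24), and Nt5e was at 1.02 (SE 0.48). Cell cycle genes were 14 higher and 24 lower (median -0.03), with Mki67 at -0.50 (SE 0.21) and E2f2 at -0.61 (SE 0.29). Apoptosis and survival genes were 16 higher and 11 lower (median 0.06), with Pmaip1 at 0.80 (SE 0.29) and Fas at 0.80 (SE 0.29). Circadian clock and ROR-responsive genes were 9 higher and 6 lower (median 0.10), with Dbp at 1.94 (SE 0.83) and Arntl, a classical target of RORα, at -0.61 (SE 0.27).

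Fatty acid genes were 11 higher and 8 lower (median log2 fold change 0.09). Over the list alone, Slc25a20 and Cpt1a passed as higher and Scd2, a fatty acid desaturase gene, as lower (-1.02, SE 0.30). Glycolysis genes were 7 higher and 13 lower (median -0.05; Slc16a3 -0.71, SE 0.36; Hk2 -0.74, SE 0.41), and oxidative phosphorylation genes were 32 higher and 9 lower (median 0.05; Ndufa4 -0.39, SE 0.18; Atp5o 0.25, SE 0.17). Interferon response genes were 16 higher and 15 lower (median 0.02), with Ifit1 at 1.75 (SE 0.61) and Mx1 at 1.41 (SE 0.61). Immediate early and dissociation stress genes were 12 higher and 12 lower (median -0.01); Hspa1b passed over the list alone, and Zfp36 was at 0.38 (SE 0.15). TGF-beta pathway genes were 7 higher and 9 lower (median -0.08; Furin -1.60, SE 0.61; Smad2 0.42, SE 0.21), and the oestrogen receptor list was 1 higher and 6 lower (median -0.29; Nrip1 -0.79, SE 0.38; Rara -0.48, SE 0.26).

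Markers of other cell types were compared in the same way. T cell markers were 7 higher and 4 lower (median log2 fold change 0.07; Cd3d 0.37, SE 0.30; Cd3g 0.24, SE 0.21) and summed to 1259 ± 169 and 1293 ± 242 CPM. B cell markers were 1 higher and 2 lower (median -0.14; Ighm -0.22, SE 0.15; Cd79b -0.14, SE 0.42), summing to 457 ± 41.4 and 394 ± 19.8 CPM. Macrophage and Kupffer cell markers were 2 higher and 1 lower (median 0.38, mean -0.08; Ccr2 0.38, SE 0.18; Csf1r -1.07, SE 0.51). Dendritic cell and MHC class II genes were 5 higher and 2 lower (median 0.38, mean -0.05; Xcr1 -2.48, SE 0.86; Itgax -0.60, SE 0.27), summing to 265 ± 33.1 and 220 ± 20.5 CPM. For the B cell and dendritic cell sums every tamoxifen library lay below every oil library (exact permutation test, two-sided, p = 0.1 for both). Ighm made up most of the B cell sum, at 439 ± 42.7 CPM in oil and 377 ± 14.6 in tamoxifen. Itgax made up most of the dendritic cell sum, at 173 ± 63.5 and 114 ± 24.2 CPM. The sums therefore do not show fewer B cells or dendritic cells. Hepatocyte markers were 2 higher and 1 lower (median 0.56; Apoe -1.07, SE 0.51; Trf 0.56, SE 0.28), summing to 38.6 ± 11.7 and 48.6 ± 4.47 CPM, and liver endothelial markers 2 higher and 1 lower (median 0.00, mean -0.04; Pecam1 -0.20, SE 0.25; Egfl7 0.08, SE 0.64). Erythroid and platelet markers were 0 higher and 4 lower (median -0.56; Hbb-bt -0.88, SE 1.06; Alas2 -0.59, SE 1.05), although camera put the list upwards, and summed to 237 ± 297 CPM in oil and 169 ± 83.2 CPM in tamoxifen. ILC2 markers were 0 higher and 5 lower (median -0.30; Il1rl1 -1.01, SE 1.17; Hes1 -0.30, SE 0.37), and ILC3 markers 1 higher and 2 lower (median -0.24, mean 1.28 through Lif, which passed over the list alone; Kit -0.50, SE 0.32). For cytokine receptors and JAK-STAT genes the mean (0.02) and camera pointed up and the median down. No neutrophil marker had enough counts to be tested.

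**Figure D3:**
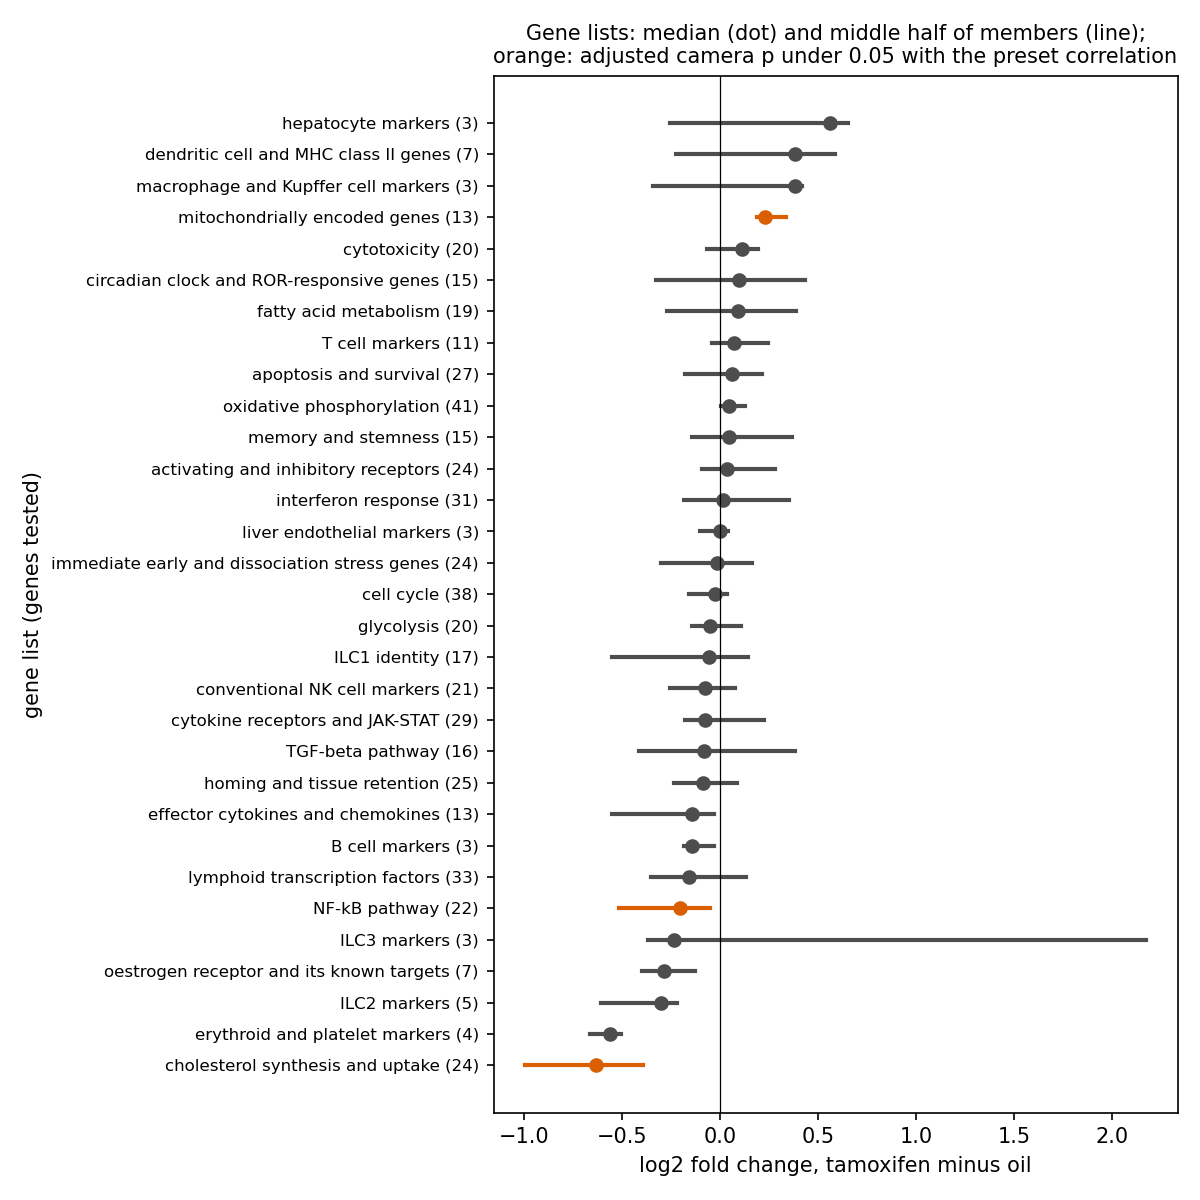
Median log2 fold change, tamoxifen minus oil, of each of the 31 gene lists tested (dots), with lines from the lower to the upper quartile of the members and the number of genes tested in parentheses. Orange marks the 3 lists called by camera with its preset correlation, of which the cholesterol list had the lowest median (-0.63).

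The authors' deposited table carries the authors' own test of the same contrast. In that deposited table, by the authors' test, 23 genes had q under 0.05, 10 higher and 13 lower in tamoxifen, and 490 had p under 0.05. Serpine2 led it (6.33-fold higher mean FPKM in tamoxifen in the authors' deposited table, q = 3.53e-13), followed by Asb2 (49.4 and 10.4, q = 4.18e-09) and Fignl1 (21.7 and 4.64, q = 1.79e-07). Of the 23, 16 were tested here and all 16 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. The other 7 were Gemin4, Gm21981, Zbtb9, Adnp, Hspa1a, Igflr1 and Ctsh, which the filter on low counts left out. Gemin4 had 2, 1 and 3 counts in the oil libraries and 286, 2 and 158 in the tamoxifen libraries, and Zbtb9 had 0 in every oil library and 0, 141 and 85 in the tamoxifen libraries. Across 10811 genes, which are not independent replicates, the log2 ratio of the authors' mean FPKM and the log2 fold change fitted here had a Pearson correlation of 0.9997.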

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

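The covariate for the length trend was the only alternative chosen after seeing the data. Serpine2 was higher in each of its 18 alternatives (log2 fold change 2.38 to 3.12) and passed in 12. The count of genes past the threshold, 1 in the report, was 18 with DESeq2, 6 with no filter on low counts, 2 among protein-coding genes and 11 with the length covariate (5 higher, 6 lower), each including Serpine2. It was 0 with limma on log2(FPKM + 1), on log2(FPKM + 0.1) and on log2(FPKM + 1) with no filter, with 375, 366 and 635 genes at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 6 genes: 2, 3 and 4 without oil replicates 1, 2 and 3, and 6, 1 (Gemin4) and 0 without tamoxifen replicates 1, 2 and 3. RLE and upper-quartile factors, limma-voom, the filter of 10 counts and the 2-fold threshold gave 1 each, and the causes of the differences were not tested. Rora was lower in all 18 alternatives (log2 fold change -0.61 to -0.28) and passed in none.

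The sample descriptions number the libraries alike in both groups, skipping 2, so their numbers differ from the replicate numbers used here. No label states a pairing. Whether the replicate numbers pair the libraries was not settled by correlating, across genes, the deviations of libraries from their group means. Same-numbered libraries gave -0.07, 0.27 and 0.16, and the 0.27 of replicate 2 was the highest of all pairs. Oil replicate 1 correlated best with tamoxifen replicate 2 (0.11). Oil replicate 3 correlated about equally with tamoxifen replicates 1 (0.165) and 3 (0.164). With the replicate block edgeR called 0 genes (564 at an unadjusted p under 0.05; Serpine2 adjusted p = 0.0677), and camera called the same 3 lists.

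Of 31 lists, 0 were called with an estimated correlation (adjusted p 0.0518 for cholesterol, 0.686 for NF-kB and 0.826 for mitochondrially encoded genes) and 1, cholesterol, by fry, which does not compare a list with other genes (adjusted p 0.629 for NF-kB and 0.827 for mitochondrially encoded genes). Leaving out 1 library gave 1 to 4 lists, with an adjusted p of 0.0042 to 0.062 for NF-kB and 3.35e-08 to 0.403 for mitochondrially encoded genes. By camera with the preset correlation, the length covariate left cholesterol and, close to the threshold, NF-kB (adjusted p 0.0473). Mitochondrially encoded genes then had an adjusted p of 0.0884. On log2(FPKM + 1), 28 lists had enough genes and 4 were called.

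Of 72 named genes, 15 passed under at least 1 alternative and 4 changed sign, none of them called. Hbb-bt was at 1.28 with limma-voom, 0.21 with the block, 0.47 on log2(FPKM + 1) with or without the filter and 1.5 on log2(FPKM + 0.1); Alas2 was at 0.93 with limma-voom, 0.11 with the block and 0.49 on log2(FPKM + 0.1). Over fits without 1 library, Hbb-bt ranged from -1.46 to 1.18, Alas2 from -1.44 to 1.06, Cd79b from -0.39 to 0.18 and Egfl7 from -0.20 to 0.42. At this depth and spread, the simulation called 27.3% of 2-fold changes, so an uncalled gene of that size is not shown to be unchanged.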

Other observations

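The tests of gene length and hepatocyte RNA, both tests of NK cells, the KEGG terms and the 5 further gene lists were chosen after the values they bear on had been seen; for the lists these were the genes that led to them and the members they share with lists of the report. Genes that glucocorticoids induce in lymphocytes had mostly higher estimates after tamoxifen. Tsc22d3, which encodes GILZ, stood at 208 ± 21.7 CPM in oil and 404 ± 21.8 in tamoxifen (log2 fold change 0.96, SE 0.16), Sgk1 at 88.5 ± 16.4 and 149 ± 9.58, and Txnip at 64.1 ± 14.3 and 112 ± 16.8, none of them past edgeR's adjusted threshold. Of 19 other glucocorticoid-responsive genes, 15 had higher estimates (mean log2 fold change 0.38), among them Fkbp5 (0.51, SE 0.24), Zfp36l2 (0.53, SE 0.24), Dusp1 (0.39, SE 0.17) and Il7r (1.01, SE 0.33), and camera with a preset correlation gave p = 5.85e-05 (adjusted p = 2.93e-04 over the 5 lists; adjusted p = 0.06 with an estimated correlation). Of the 19, 8 belong to lists of the report, and the other 11 had a mean of 0.35 (10 higher; adjusted camera p = 0.0109, and adjusted p = 0.204 with an estimated correlation). No member of the 5 further lists passed edgeR's test when adjusted over its list alone. A broader glucocorticoid response is a candidate explanation that rests on the preset correlation, and hormone levels were not measured here.

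Fatty acid oxidation genes mostly had higher estimates as well. Beside Cpt1a and Slc25a20, 19 of 22 other PPAR-responsive oxidation genes had higher estimates (mean log2 fold change 0.21), led by Etfdh (0.62, SE 0.19) and Acaa2 (0.54, SE 0.17); 9 of the 22 belong to the fatty acid list of the report, and the other 13 had a mean of 0.17 (adjusted camera p = 0.0295, and adjusted p = 0.33 with an estimated correlation). Camera gave p = 4.21e-04 with the preset correlation (adjusted p = 0.00105) and adjusted p = 0.173 with an estimated correlation, so that a coordinated rise may be present but rests on the preset value. The matching KEGG terms did not pass by camera with the preset correlation: fatty acid degradation (30 genes, median 0.11, adjusted p = 0.23), PPAR signalling (29 genes, median 0.06, adjusted p = 0.933) and fatty acid metabolism (41 genes, median 0.07, adjusted p = 0.976). Of 289 KEGG terms in the deposited table, camera with the preset correlation called 2, steroid biosynthesis (15 genes, median log2 fold change -0.29, adjusted p = 0.00689) and ribosome (126 genes, median 0.12, adjusted p = 0.0414). With an estimated correlation it called 0 (adjusted p = 0.998 for both), and with the length covariate the ribosome term had adjusted p = 0.977. The term cholesterol metabolism, with 21 genes, had a median of -0.02 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.886). For the term NF-kappa B signalling, with 68 genes, the median was -0.08 (camera with the preset correlation, adjusted p = 0.815).

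For the lower cholesterol genes, the length trend of each library was added as a covariate. The mean log2 fold change of the list was then -0.66, or 99.0% of its value without it. The mean slopes of the groups lay close together (0.02 in oil, -0.02 in tamoxifen), so this fit could hardly have moved the estimate. Oil replicates 1, 2 and 3 had slopes of 0.04, 0.12 and -0.10, yet list levels of 0.07, -0.04 and -0.03 (log2, relative to oil). That flat level argues against a length effect as the whole cause. Hepatocyte markers summed to 38.6 CPM in oil, 6.83% of the 565 CPM by which the cholesterol list was higher there, too little for liver RNA to have carried the difference. Among biological explanations, lower SREBP activity is a candidate: 14 of 17 other SREBP-responsive lipid genes, 7 of them in the fatty acid list of the report, had lower estimates (mean log2 fold change -0.39, median -0.25, camera p = 0.00261; adjusted p = 0.173 over the 5 lists with an estimated correlation), with a mean of -0.21 without Acsl3 (adjusted camera p = 0.0323; adjusted p = 0.252 with an estimated correlation). The 10 genes outside that list had a median of -0.12 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0329), and without Acsl3 a mean of -0.17 (adjusted p = 0.269), so that the test rests in part on that gene. LXR targets, which sterol excess would raise, had a mean of -0.22 (SE 0.13; camera with Benjamini-Hochberg adjustment, adjusted p = 0.0575), and the 7 of them in no list of the report a mean of -0.03 (adjusted p = 0.832), which leaves sterol excess open, as does the design for tamoxifen itself and any gene deletion it may have induced.

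Phlda3, Cdkn1a (39.1 ± 6.08 and 67.5 ± 4.25 CPM) and Ccng1 (85.4 ± 16.8 and 144 ± 20.7 CPM), textbook p53 targets, had a mean log2 fold change of 1.48. With the length covariate it was 1.68, or 113.3% of that value. The mean slopes of the groups lay close together (0.02 in oil, -0.02 in tamoxifen), so this fit could move the value little. It is therefore only weak evidence against a length effect. Of 26 other p53 targets, 5 of them in lists of the report, 17 had higher estimates, with a mean log2 fold change of 0.18 (camera p = 0.041; adjusted p = 0.0512 over the 5 lists; adjusted p = 0.252 with an estimated correlation; adjusted p = 0.0107 with the length covariate). The 21 that are in no list of the report had a mean of 0.11 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.443). The KEGG term for p53 signalling, with 60 genes, had a median of -0.01 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.994), so that a broader p53 response remains a possible explanation on which these tests differ.

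Cxcr6 and Itga1, with a mean log2 fold change of -1.33, could be lower because more conventional NK cells were sorted. A first test, on the NK cell marker list, did not decide (mean log2 fold change -0.07, SE 0.11). Itgam entered it under 2 models, at -0.71 (SE 0.35) and, with few counts, at 1.66 (SE 1.32). The model with few counts raised the mean, and the list was not tested without it. The first test was then replaced by a test on 8 ILC1 markers that NK cells lack or hold at low levels. These were Tnfsf10, Cd200r1, Il7r, Zfp683, Inpp4b, Tmem176a, Tmem176b and Rora, picked with their values already seen. Others were left out, such as Xcl1 (-0.70, SE 0.30), Ltb (-0.55, SE 0.41) and Il21r (0.36, SE 0.34). The mean of the 8 was -0.004 (SE 0.187, 4 higher and 4 lower). Il7r (1.01, SE 0.33), also among the glucocorticoid-responsive genes above, was the highest of them. More NK cells would have lowered markers that NK cells lack about as much as Cxcr6 and Itga1, and markers they hold at low levels by less. How much less was not measured here. The ILC1 identity list of the report, with 17 genes, had a mean of -0.22 with Cxcr6 and Itga1 included. The 8 markers cannot decide for or against the explanation, as they were chosen with their values seen after the first test was undecided. A change within ILC1s remains a hypothesis.

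The first principal component of the libraries held 33.6% of the variance without separating the groups, and its loadings correlated with gene model length across genes (Spearman rho = -0.35; genes are not independent replicates). The second held 20.5% and separated them (5.31, 14.5 and 37.5 in oil, -8.96, -15.6 and -32.8 in tamoxifen). The length slopes were 0.04, 0.12 and -0.10 in the oil libraries and -0.06, 0.06 and -0.05 in the tamoxifen libraries (exact permutation test, two-sided, p = 0.7). Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 5 gave at least the 1 gene of the real split, and the highest other gave 507; that split parts the 3 libraries with positive slopes (oil replicates 1 and 2, tamoxifen replicate 2) from the 3 with negative ones, which points to a structure of the samples. With the slope as a covariate, tamoxifen against oil gave 11 genes, among them Tsc22d3, Serpine2, Cxcr6, Asb2, Phlda3, 9030617O03Rik, Jmjd8, Ccng1, Fignl1 and Xcl1. For lists, 5 of the 10 splits gave at least the 3 of the real one, and the highest other gave 7. For the cholesterol list, 1 split, the real one, had a camera p as small as 6.8e-16, and the smallest of the others was 2.21e-04.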
